A study of Mus musculus with 18 samples.

How the data were processed

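Total RNA from mouse heart tissue was depleted of ribosomal RNA and sequenced in 18 libraries, 6 each of control, MI and HXP mice. The labels give the group of each library and no sex, age or times. The authors deposited 1 file per library with a value for each of 34150 Ensembl genes, and the deposited values are in FPKM, a unit inferred from the values because the file headers do not name it: each value times the merged exon length of its gene fell on whole multiples of 1 step per library (96.5% to 97.2% of 14598 to 16523 values checked per library, within 0.1 of a whole read). Per the submitters' processing notes the genome build was GRCm38 and limma was used, with no role or version given. The aligner, the counting tool and the annotation are not given in the sources used here.

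The IDs were matched to the GENCODE M21 annotation on GRCm38 (34097 matched, 53 not), which gave symbols, coordinates and exon lengths. From the steps, 75.8 to 81.1 M reads per library were recovered, so that the precision of all but the lowest values was set by the spread between libraries and not by counting. The recovered reads served for the read shares, for 1 alternative and for no main result. The mitochondrial share covers 15 mitochondrial genes and 7 nuclear copies of mitochondrial genes at 1000 FPKM or more.

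Values were analysed as log2(FPKM + 1) for the 13710 genes with a mean of at least 0.5 FPKM over the 18 libraries. A single linear model with 3 groups was fitted with limma 3.58.1 in R 4.3.3 (trend on, robust prior off), with the contrasts MI minus control, HXP minus MI and HXP minus control. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are fitted differences of log2(FPKM + 1), given with their standard error, so that they are compressed for genes near 1 FPKM. The p-values measure the spread between these libraries, pooled over the 3 groups. That spread holds differences between mice together with those of dissection and library preparation. The groups, the comparisons, the tests, 35 gene lists and the settings said below to be chosen in advance were fixed before the data were examined.

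The lists cover cardiac programs, metabolism, matrix, signalling, immune and stress responses, and markers of other cell types that heart tissue could hold. Lists with at least 5 measured members (33 of 35) were tested against all other genes with limma camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and by an exact permutation test of the mean of the list per library (924 regroupings). Members were counted over all genes tested and adjusted over the list alone.

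Named genes were taken, for each comparison, from 16 genes fixed in advance (Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn, Timp1, Il1b, Il6, Ccl2, Spp1, Axin2, Ctnnb1 and Ccnd1), then the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 1 FPKM and a symbol that is not a predicted gene name, then list members in order of p. Where no gene was called, the 6 smallest p of each sign stood in. About 30 genes per comparison follow that rule, and not every gene it picks is given. Further list members (Ms4a7, Fcgr1, Cd74, Ctss, Cd36, Hadhb, mt-Co3, mt-Nd1, Tgfb3, Sfrp1, Aurka, Top2a, Igkc, Egr2 and Cx3cl1 in MI against control, and Arntl, Dusp1, Tgfb1, mt-Nd6 and Per3 in HXP against MI) were chosen as examples after their values were seen, as were the 30 lower genes as a set and the clock genes of the closing part.

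Other settings chosen in advance were quantile normalization, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, a robust prior, the compared groups only, the replicate number as a block, the run of the library numbers as a covariate, an estimated correlation for the lists and leaving out each library. Settings for counts were not run, since the values are FPKM. Settings chosen after seeing the data were scaling to non-mitochondrial reads, median-ratio scaling, a correction of the trend with GC content (lowess, span 0.3) alone and with other settings, voom on the recovered reads, leaving out HXP 5 and HXP 6, averaging MI 1 and MI 2, and the run of 10 libraries alone. The fit was tested on simulated data with 200 changed genes in 10 sets per comparison: 81.5% to 84.0% of log2 changes of 1 and 96.7% to 97.2% of log2 changes of 2 were called, with 4.53% to 4.96% false calls. The changed genes were drawn at random from those with a mean log2(FPKM + 1) above 1, so the shares do not cover lower genes. The simulated noise was independent between genes and of equal spread in the 3 groups. Other splits of the 12 libraries of each comparison were drawn 100 times of 462. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main results.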

Results

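RNA of mouse heart tissue, depleted of ribosomal RNA, was sequenced in 18 libraries, 6 from control mice, 6 from mice with myocardial infarction (MI) and 6 from HXP mice. The series title places the HXP treatment in a mouse model of acute MI. What HXP abbreviates, its dose and the times of infarction, treatment and collection are not given in the sources used here, nor whether each HXP mouse had an infarct. Each library held 75.8 to 81.1 M reads, as recovered from the steps of its FPKM values, and 9888 to 12820 genes at 1 FPKM or more. Mitochondrial genes and their nuclear copies took 36.4% to 42.7% of the recovered reads in control, 20.4% to 33.2% in MI and 20.6% to 45.5% in HXP. The library numbers in the file headers fell into 3 runs. The first held 3 libraries (control 2, control 5 and MI 5) and the next 5 (control 1 and HXP 1, 3, 4 and 6). The last held 10 (control 3, 4 and 6, MI 1, 2, 3, 4 and 6, HXP 2 and 5).

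The comparison of MI with control asks which genes differ in the infarcted heart. Genes of the cardiac stress and fetal program rose in MI. Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, GRCm38 chromosome 4, 148000722 to 148002079), rose from 190.4 ± 95.6 FPKM in control to 4509 ± 3122 FPKM in MI (SD, n = 6 each). Its log2 fold change was 4.35 (SE 0.80, limma adjusted p = 0.0127). Myh7, the beta myosin heavy chain of the fetal heart, rose from 51.1 ± 9.33 to 260.5 ± 148 FPKM (SD, n = 6 each, log2 fold change 2.17, SE 0.44, limma adjusted p = 0.0137). Nppb rose by a log2 fold change of 1.88 (SE 0.41, limma adjusted p = 0.0139). For these 3 genes each of the 6 MI libraries lay above all controls. Acta1, skeletal alpha actin, had a log2 fold change of 1.34 (SE 0.48, limma adjusted p = 0.0360). Its limma adjusted p ran from 0.0113 to 0.130 over the alternatives, above the threshold without any 1 of control 2, 4, 5 and 6 and MI 1, 3, 4 and 5. Of these libraries, MI 4 also held skeletal muscle markers (mean 3.83 on the log2 scale, against at most 1.05 in the other MI libraries). Of the 11 measured members of the cardiac stress and fetal program, 10 rose over all genes tested and 11 adjusted over the list alone (median log2 fold change 1.38, limma camera adjusted p = 0.00325, adjusted p = 0.738 with an estimated correlation). Myh6, the adult alpha myosin heavy chain, stood at 3050.0 ± 386 FPKM in control and 2441 ± 493 FPKM in MI (SD, n = 6 each). Its log2 fold change of -0.34 (SE 0.19) did not pass (limma adjusted p = 0.146).

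Extracellular matrix genes had the highest fold changes. Of the 36 genes in this list 36 rose, over all genes and adjusted over the list alone. Their median log2 fold change was 3.22 (limma camera adjusted p = 1.18e-14, adjusted p = 0.624 with an estimated correlation). The mean of the list per library was 5.44 ± 0.92 in MI and 2.07 ± 0.16 in control on the log2 scale (SD, n = 6 each, exact permutation p = 0.00216, the smallest that the 924 regroupings can give). Col1a1, the main fibrillar collagen chain (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), rose from 13.5 ± 2.60 to 275.6 ± 204 FPKM (SD, n = 6 each, log2 fold change 3.98, SE 0.82, limma adjusted p = 0.0139). Postn, which encodes the matrix protein periostin (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), rose from 3.14 ± 0.618 to 88.4 ± 53.1 FPKM (SD, n = 6 each, log2 fold change 4.20, SE 0.69, limma adjusted p = 0.0127). The cartilage matrix gene Comp (ENSMUSG00000031849, chromosome 8, 70373558 to 70382066) had the highest log2 fold change of the named genes, 6.43 (SE 1.02). It was followed by Sfrp2 at 5.37 (SE 0.97), Fmod at 5.36 (SE 0.81), Angptl7 at 5.06 (SE 0.84), Cilp at 4.71 (SE 0.79) and Ltbp2 at 4.60 (SE 0.74), each with a limma adjusted p of 0.0127. Col3a1 (3.83), the metalloproteinase inhibitor gene Timp1 (3.82), Thbs4 (4.45) and the osteopontin gene Spp1 (2.99) rose too, by log2 fold changes with limma adjusted p from 0.0127 to 0.0142.

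Lists linked to these cells and signals rose in MI as well. Among fibroblast markers 12 of 14 rose over all genes and 13 adjusted over the list alone (median log2 fold change 1.72, limma camera adjusted p = 0.00226, adjusted p = 0.738 with an estimated correlation). Mfap5 rose by 3.15 (SE 0.51). In TGF-beta signalling 16 of 19 rose over all genes and 17 adjusted over the list alone (median 1.15, limma camera adjusted p = 0.000650, adjusted p = 0.738 with an estimated correlation). Among them was the ligand gene Tgfb3 (2.79). In Wnt signalling 22 of 36 rose over all genes and 23 adjusted over the list alone (median 0.52, limma camera adjusted p = 0.00127, adjusted p = 0.810 with an estimated correlation). Its members with the highest fold changes among those named were Sfrp2, Dkk3 (4.19) and Sfrp1 (3.08), of which Sfrp2 and Sfrp1 encode secreted proteins known to bind Wnt ligands. The beta-catenin gene Ctnnb1 rose by 0.45 (SE 0.12, limma adjusted p = 0.0148), but after median-ratio scaling its log2 fold change Ctnnb1 MI vs control was 0.08 (limma adjusted p = 0.406, from 0.000939 to 0.533 over the alternatives). The Wnt target genes Axin2 (0.23, SE 0.11, limma adjusted p = 0.0989) and Ccnd1 (0.27, SE 0.17, limma adjusted p = 0.190) did not pass. Mesothelial and epicardial markers rose in 8 of 9 members over all genes and 9 adjusted over the list alone (median 1.498, limma camera adjusted p = 0.0161, adjusted p = 0.738 with an estimated correlation).

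Immune and cell division genes made up further groups. Macrophage and monocyte markers rose in 21 of 27 members over all genes and 23 adjusted over the list alone (median log2 fold change 1.27, limma camera adjusted p = 0.00297, adjusted p = 0.810 with an estimated correlation). Ms4a7 rose by 1.60 (SE 0.38) and the Fc receptor gene Fcgr1 by 1.16 (SE 0.29). In MHC class II presentation 10 of 10 members rose, over all genes and adjusted over the list alone (median 1.51, limma camera adjusted p = 0.0364, adjusted p = 0.816 with an estimated correlation). The invariant chain gene Cd74 rose by 1.72 and the protease gene Ctss by 2.17. This list's limma camera adjusted p was 0.0552 without control 6 and 0.0551 without MI 3. In the cell cycle list 16 of 17 rose, over all genes and adjusted over the list alone (median 0.60, limma camera adjusted p = 0.0258, adjusted p = 0.826 with an estimated correlation). Aurka (0.60) and Top2a (0.67) were among them, and the limma camera adjusted p was 0.0552 without control 6. The cytokine genes Il1b (0.60, SE 0.32, limma adjusted p = 0.132) and Ccl2 (0.49, SE 0.29, limma adjusted p = 0.173) did not pass. Il6, with a mean of 0.409 ± 0.251 FPKM in MI, 0.187 ± 0.362 in HXP and 0.00715 in control (SD, n = 6 each), lay below the filter on low values.

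Lists of energy metabolism and excitation lay lower than other genes in MI by limma camera at the preset correlation, though part of their members did not pass and 0 of these lists passed with an estimated correlation. In fatty acid oxidation 13 of 23 members fell and 1 rose over all genes, 15 and 1 adjusted over the list alone (median log2 fold change -0.44, limma camera adjusted p = 4.12e-18, adjusted p = 0.325 with an estimated correlation). Among those lower were Hadhb, of the mitochondrial trifunctional protein (-0.62, SE 0.20), and the fatty acid transporter gene Cd36 (-0.44, SE 0.13). Nuclear oxidative phosphorylation genes fell in 3 of 33 members over all genes and 0 adjusted over the list alone. Of its 33 members 32 had a negative fold change (median -0.32, limma camera adjusted p = 1.85e-20, adjusted p = 0.325 with an estimated correlation). Mitochondrially encoded transcripts fell in 6 of 13 members over all genes and 10 adjusted over the list alone (median -0.46, limma camera adjusted p = 5.21e-14, adjusted p = 0.325 with an estimated correlation). The mitochondrial transcripts mt-Co3 (-0.63, SE 0.19) and mt-Nd1 (-0.59, SE 0.18) and the mitochondrial ribosomal RNA mt-Rnr2 (-1.003, SE 0.28) fell. Of cardiac ion channels 4 of 18 fell, over all genes and adjusted over the list alone (median -0.15, limma camera adjusted p = 3.88e-08, adjusted p = 0.325 with an estimated correlation). The potassium channel subunit gene Kcnv2 fell by 1.01 (SE 0.20). In the list of cardiomyocyte contractile and calcium handling genes 3 of 22 fell over all genes and 0 adjusted over the list alone (median -0.11, limma camera adjusted p = 3.58e-07, adjusted p = 0.446 with an estimated correlation). The carboxylesterase gene Ces1d (ENSMUSG00000056973, chromosome 8, 93166068 to 93197838) fell from 39.2 ± 4.29 to 13.4 ± 8.22 FPKM (SD, n = 6 each, log2 fold change -1.62, SE 0.30, limma adjusted p = 0.0127). It was followed by the sodium channel subunit gene Scn4b (-1.39) and by Lrtm1 (-1.05). Single libraries ended some of these calls: Hadhb, Cd36, mt-Co3 and mt-Nd1 did not pass without MI 5, the library that also held lung epithelial markers (mean 5.41 on the log2 scale, against at most 0.28 in the other MI libraries). In exact permutation tests of the mean per library 26 of 33 lists passed after adjustment in MI against control. These means keep the shift of 0.27 (log2) in the median of all genes. Cardiac ion channels (exact permutation p = 0.0779, adjusted to 0.0918) and the contractile and calcium handling list (0.0563, adjusted to 0.0688) did not.

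**Figure D1:**
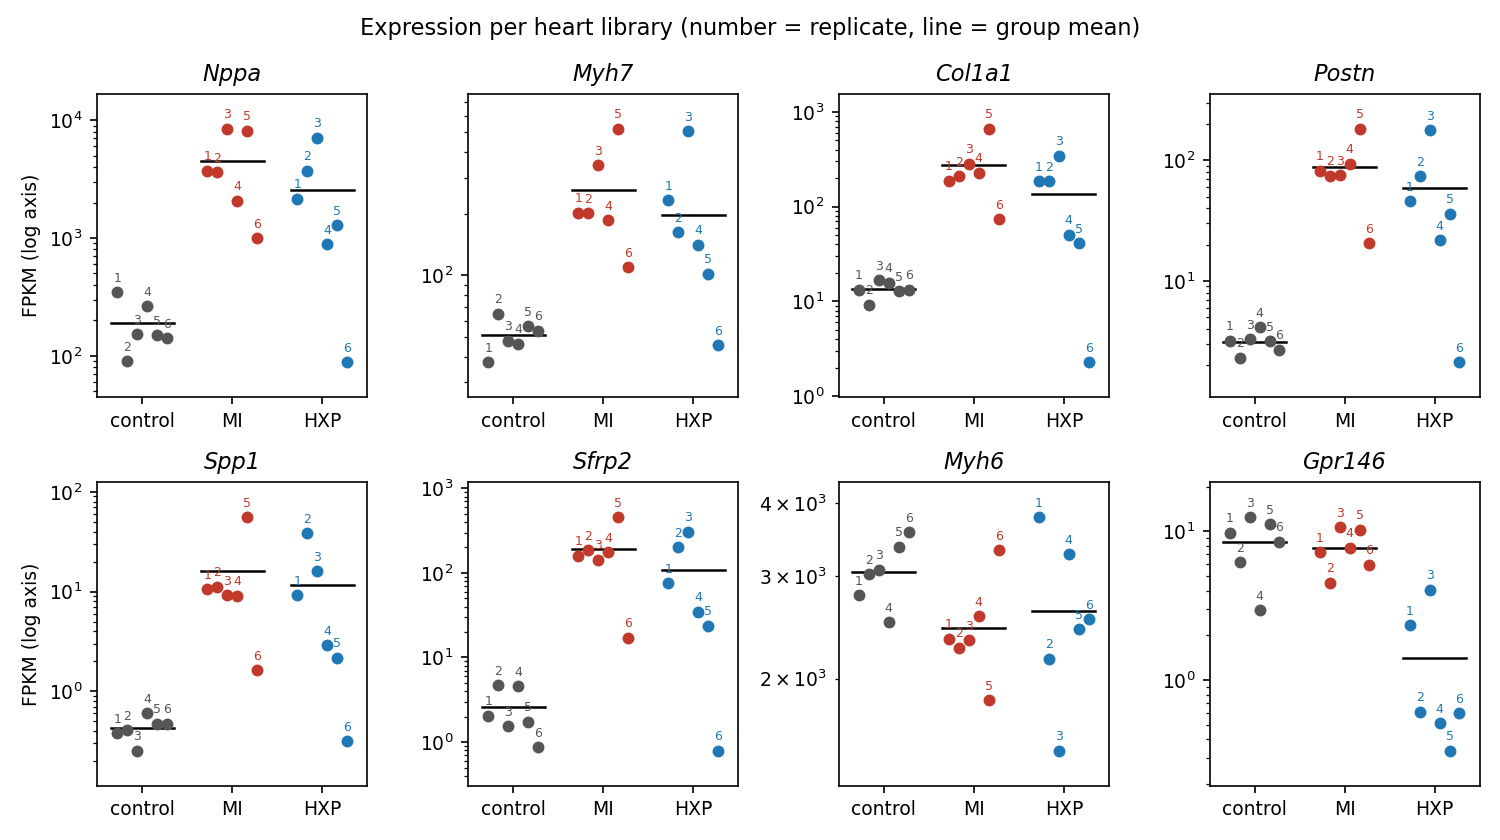
FPKM on a log axis of 8 genes in each of the 18 libraries, by group, with the replicate number at each point and a line at the group mean (n = 6 each). In Nppa, Myh7, Col1a1, Postn, Spp1 and Sfrp2 each of the 6 MI libraries lies above all controls, while the HXP libraries spread from HXP 6, within or below the controls, to the MI level.

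Over all genes, limma called 5934 of 13710 in MI against control, 5494 higher and 440 lower, of which 864 were at least 2-fold higher and 6 at least 2-fold lower. The median of all genes was itself shifted by 0.27 (log2). The split depended on the scaling: 1810 higher and 2371 lower after quantile normalization, 3017 and 1294 after scaling to non-mitochondrial reads, and 2331 and 2063 after median-ratio scaling. Without MI 5 the count was 2656 and without control 2 it was 3892. Within the run of 10 libraries, with 3 controls and 5 MI, limma called 79 genes, and with the run as a covariate 4223. The other runs held too few libraries of these groups for a value of their own.

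The comparison of HXP with MI asks which genes differ between the HXP and MI groups. Mean levels of the stress and matrix genes were lower in HXP than in MI, with a wide spread between HXP libraries, and none passed the test. Nppa stood at 2540.0 ± 2558 FPKM in HXP (SD, n = 6), a log2 fold change of -1.40 against MI (SE 0.80, limma adjusted p = 0.416). Col1a1 stood at 135.0 ± 129 FPKM (SD, n = 6), a log2 fold change of -1.76 (SE 0.82, limma adjusted p = 0.359). Col1a1 stood at 345 FPKM in HXP 3, 186 in HXP 2 and 185 in HXP 1, within the MI range of 74.1 to 668 FPKM. It was 50.7 in HXP 4, 41.3 in HXP 5 and 2.29 in HXP 6, the last below the lowest control at 9.25. Log2 fold changes against MI were -0.79 for Nppb, -0.59 for Myh7, -0.40 for Acta1, -1.20 for Col3a1, -1.13 for Postn, -1.31 for Timp1 and -0.71 for Spp1. They were -0.24 for Il1b, -0.13 for Ccl2, 0.06 for Myh6, -0.08 for Axin2, -0.17 for Ctnnb1 and -0.26 for Ccnd1. Limma adjusted p ran from 0.359 to 0.877 over these fixed genes.

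The genes with the smallest p in HXP against MI did not pass either. Slbp, which encodes the histone mRNA stem-loop binding protein (ENSMUSG00000004642, chromosome 5, 33634952 to 33652574), stood at 1.18 ± 0.225 FPKM in HXP and 1.95 ± 0.116 FPKM in MI (SD, n = 6 each). Its log2 fold change was -0.44 (SE 0.07, limma adjusted p = 0.102), with 6 of 6 HXP libraries below every MI library. The orphan receptor gene Gpr146 (ENSMUSG00000044197, chromosome 5, 139377697 to 139396415) stood at 1.41 ± 1.49 FPKM in HXP and 7.73 ± 2.40 FPKM in MI (SD, n = 6 each). Its log2 fold change was -2.002 (SE 0.34, limma adjusted p = 0.102), again with 6 of 6 HXP libraries below every MI library. Without HXP 3 both Slbp and Gpr146 passed at a limma adjusted p of 0.00555. Over the alternatives the limma adjusted p ran up to 0.592 for Gpr146 and 0.973 for Slbp. The glutathione transferase genes Gstm1 (0.47, SE 0.09, limma adjusted p = 0.173) and Gsta3 (0.48, SE 0.10, limma adjusted p = 0.196) were above every MI library in 6 of 6 HXP libraries. Further genes by the same rule were Cops2 (0.38), Ces1d (1.32), Slc41a3 (-0.85), Arhgap23 (-0.80), Arhgef19 (-0.97) and Gsg1l (-0.45), with limma adjusted p from 0.173 to 0.202. Among list members they were the Wnt receptor gene Fzd8 (-0.83), the prolyl hydroxylase gene Egln3 (-0.48) and the transcription factor gene Egr2 (-0.77), with limma adjusted p from 0.212 to 0.248.

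Matrix, signalling and immediate early genes lay lower, and clock and mitochondrial genes higher, than other genes in HXP against MI by limma camera at the preset correlation. With an estimated correlation 0 lists passed (limma camera adjusted p = 0.484 for the circadian clock and 0.928 for each other list named here), and 0 members of any list passed over all genes. Fold changes were negative in 36 of 36 extracellular matrix genes (median log2 fold change -1.27, limma camera adjusted p = 7.86e-06). They were negative in TGF-beta signalling for 19 of 19 (median -0.51, adjusted p = 0.00634), Wnt signalling for 35 of 36 (median -0.32, limma camera adjusted p = 0.000424), immediate early genes for 20 of 20 (median -0.59, adjusted p = 0.000112) and the glycolysis and hypoxia response for 19 of 20 (median -0.30, adjusted p = 0.0342). The signs alone do not set these lists apart, since the median of all genes was itself -0.12. Lists that did not pass had uniform signs too. Positive fold changes were held by 0 of 24 interferon response genes (limma camera adjusted p = 0.141) and 0 of 10 MHC class II genes (limma camera adjusted p = 0.523). Adjusted over the list alone, 6 immediate early genes, 1 Wnt gene and 1 glycolysis gene were lower and 0 matrix or TGF-beta genes. In the circadian clock list, 5 members were higher and 1 lower adjusted over the list alone (median 0.15, limma camera adjusted p = 1.95e-05). Hlf (0.84), Per3 (0.54) and Nr1d2 (0.42) lay above 0 and Arntl, which encodes the activator BMAL1, below (-0.69). Mitochondrially encoded transcripts (median 0.18, limma camera adjusted p = 4.82e-06), fatty acid oxidation (0.13, adjusted p = 0.000169), nuclear oxidative phosphorylation (0.08 with a mean of -0.003, adjusted p = 0.000420) and cardiomyocyte contractile and calcium handling genes (0.06, adjusted p = 0.0226) were higher relative to other genes, with 0 members adjusted over the list alone. In exact permutation tests of the mean per library 0 of 33 lists passed after adjustment. Only immediate early genes had an unadjusted exact p below 0.05 (0.0476, exact permutation p adjusted to 0.515).

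Several of these list calls rested on single libraries. By limma camera, TGF-beta signalling had an adjusted p of 0.0625 without MI 5. Fatty acid oxidation had 0.0788 without MI 5 and 0.0694 without HXP 6. Nuclear oxidative phosphorylation had 0.250 without MI 5 (median -0.002), 0.175 without HXP 1 and 0.205 without HXP 6. The cardiomyocyte contractile and calcium handling list had 0.0520 without MI 2, 0.0583 without MI 3, 0.432 without MI 5, 0.549 without HXP 1 (median -0.05), 0.252 without HXP 4 and 0.182 without HXP 6. The glycolysis and hypoxia response had 0.0631 without MI 3, 0.0769 without MI 4, 0.104 without MI 6, 0.105 without HXP 2, 0.151 without HXP 3 and 0.0918 without HXP 4. HXP 5 and HXP 6 had the lowest values of genes with high GC content (median log2 deviations of -0.43 and -0.78 in the highest of 5 GC bins, against -0.22 to 0.46 in the other libraries). Without both of them, an alternative chosen after seeing the data, the median of the extracellular matrix and fibrosis list was -0.42 (limma camera adjusted p = 0.000839) and that of mitochondrially encoded transcripts -0.05 (adjusted p = 0.982).

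**Figure D2:**
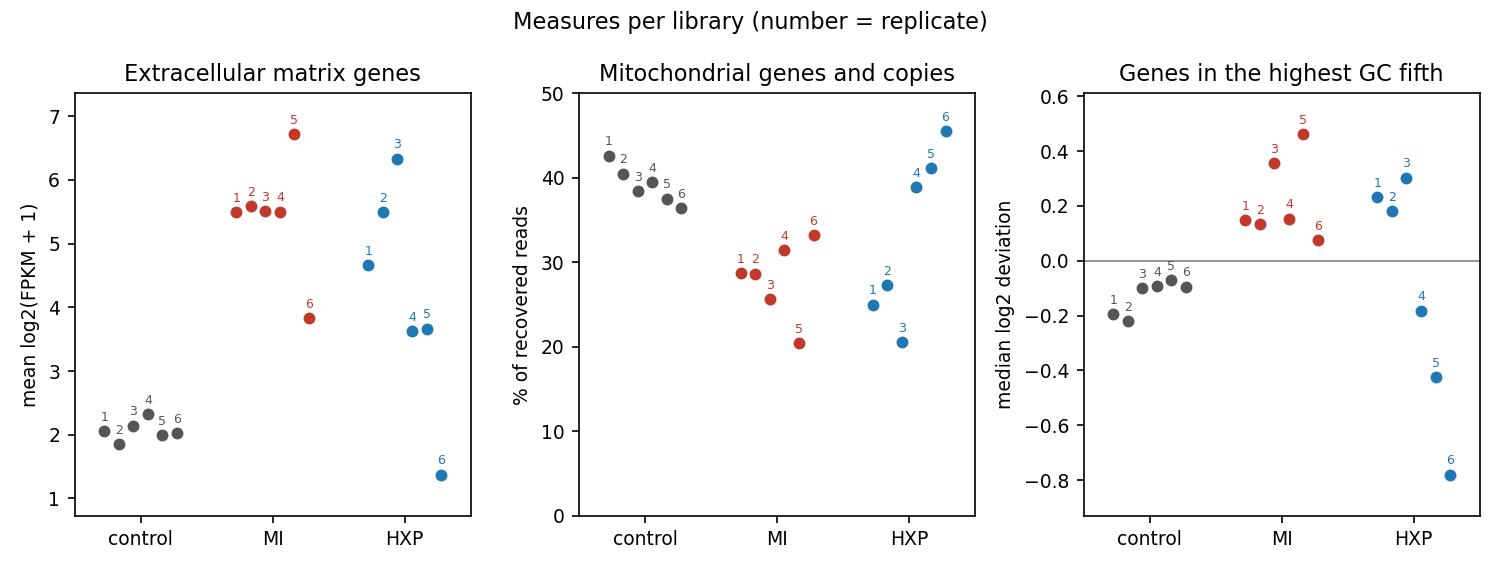
Per library and group, from left to right: the mean log2(FPKM + 1) of 36 extracellular matrix genes, the percentage of recovered reads in mitochondrial genes and their nuclear copies, and the median log2 deviation from the median library of genes in the highest of 5 bins of GC content. HXP 6 has the lowest matrix mean (1.37), the highest mitochondrial share (45.5%) and the lowest deviation (-0.78) of the 18 libraries.

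Over all genes, limma called 0 genes in HXP against MI, with 1891 at an unadjusted p below 0.05 (259 higher, 1632 lower) and a median shift of -0.12 (log2). Limma called 0 with a robust prior, 0 by voom on the recovered reads, 4 after quantile normalization, 5 after median-ratio scaling and 1 after scaling to non-mitochondrial reads. It called 71 without HXP 1, 4 without HXP 3 and 1 without MI 5. Within the run of 10 libraries, with 5 MI and 2 HXP, it called 3, and with the run as a covariate 0. In simulated data with the spread pooled over the 3 groups, 81.5% of log2 changes of 1 were called. That share is a mean over genes drawn at random from those with a mean log2(FPKM + 1) above 1. The noise was independent between genes and of equal spread in the 3 groups. The share does not hold for matrix genes, whose mean per library had an SD of 1.735 in HXP and 0.923 in MI.

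The comparison of HXP with control asks which genes differ between HXP and control hearts. The genes that were lower included Hist1h4h, a histone H4 gene (ENSMUSG00000060981, chromosome 13, 23531050 to 23531519), which fell from 12.8 ± 4.81 to 1.43 ± 1.73 FPKM (SD, n = 6 each, log2 fold change -2.65, SE 0.47, limma adjusted p = 0.0363). The mitochondrial ribosomal protein genes Mrpl34 (-2.11, SE 0.43, limma adjusted p = 0.0453) and Mrps12 (-1.75, SE 0.32, limma adjusted p = 0.0374), the mitochondrial protein gene Chchd10 (-1.39, SE 0.28, limma adjusted p = 0.0453), Macrod1 (-1.38, SE 0.26, limma adjusted p = 0.0374) and Gpr146 (-2.07, SE 0.34, limma adjusted p = 0.0293) fell too. Each of these 6 calls was lost without any 1 of control 1, 3, 5 and 6, HXP 2 and HXP 5. All 6 HXP libraries lay below every control for Hist1h4h, Mrps12, Chchd10 and Macrod1, and 5 of 6 for Mrpl34 and Gpr146. Among the genes that rose were Angptl7, a secreted angiopoietin-like protein gene (ENSMUSG00000028989, chromosome 4, 148495183 to 148500460), at 59.2 ± 87.4 FPKM against 0.480 ± 0.546 in control (SD, n = 6 each, log2 fold change 4.05, SE 0.84, limma adjusted p = 0.0456, 5 of 6 libraries above every control). Others were the translation regulator gene Cpeb1 (0.89, SE 0.18, limma adjusted p = 0.0453), Ppp1ccb (0.86, SE 0.14, limma adjusted p = 0.0293), Gsta3 (0.51), Tpd52l2 (0.51) and Maco1 (0.47), whose calls, like that of Angptl7, were lost without the same libraries.

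Stress and matrix genes stood above control in HXP without passing over all genes. Log2 fold changes were 2.95 for Nppa (SE 0.80, limma adjusted p = 0.0874), 1.58 for Myh7 (SE 0.44, limma adjusted p = 0.0881), 2.22 for Col1a1 (SE 0.82, limma adjusted p = 0.102) and 3.07 for Postn (SE 0.69, limma adjusted p = 0.0528), each above every control in 5 of 6 HXP libraries. They were 1.09 for Nppb, 0.94 for Acta1, 2.63 for Col3a1, 2.51 for Timp1, 2.28 for Spp1, 2.26 for Mfap5, 3.53 for Fmod, 2.91 for Thbs4, 0.36 for Il1b, 0.36 for Ccl2, -0.27 for Myh6, 0.15 for Axin2, 0.28 for Ctnnb1 and 0.01 for Ccnd1, with limma adjusted p from 0.0579 to 0.965. Without HXP 6 the log2 fold change Nppa HXP vs control was 3.73 and the log2 fold change Col1a1 HXP vs control 3.09, and both passed. As a list, extracellular matrix genes had 0 of 36 members past the test over all genes and 35 higher adjusted over the list alone (median 2.09, limma camera adjusted p = 3.97e-11). Fibroblast markers (9 of 14 higher adjusted over the list alone, median 1.09, adjusted p = 0.00343), mesothelial and epicardial markers (8 of 9, median 1.15, adjusted p = 0.00343), the cardiac stress and fetal program (6 of 11, median 0.87, adjusted p = 0.0240) and macrophage and monocyte markers (12 of 27, median 0.74, adjusted p = 0.0158) were higher by limma camera, each with 0 members past over all genes. So were B cell and plasma cell markers (3 of 9, median 0.74, adjusted p = 0.0314) and TGF-beta signalling (9 of 19 higher and 1 lower, median 0.67, limma camera adjusted p = 0.0461). Lower were nuclear oxidative phosphorylation (2 of 33 adjusted over the list alone, median -0.25, adjusted p = 2.86e-13), fatty acid oxidation (0 of 23, median -0.33, adjusted p = 3.42e-11), and cardiac ion channels (2 of 18, median -0.32, limma camera adjusted p = 1.33e-09). Lower too were mitochondrially encoded transcripts (0 of 13, median -0.28, adjusted p = 4.26e-06) and cardiomyocyte contractile and calcium handling genes (2 of 22 lower and 1 higher, median -0.04, adjusted p = 0.000310). With an estimated correlation the adjusted p was 0.779 for each of these 12 lists by limma camera. In exact permutation tests of the mean per library 0 of 33 lists passed after adjustment, 12 of them having an unadjusted exact p below 0.05.

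Single libraries ended 3 of these list calls by limma camera. The cardiac stress and fetal program had an adjusted p of 0.0621 without control 6, and B cell and plasma cell markers 0.0573 without HXP 3. TGF-beta signalling lost its call without any 1 of control 2, 3, 4 and 6, MI 1, 2 and 3 and HXP 1, 2, 3 and 4, with adjusted p from 0.0504 (control 3) to 0.0715 (HXP 3).

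**Figure D3:**
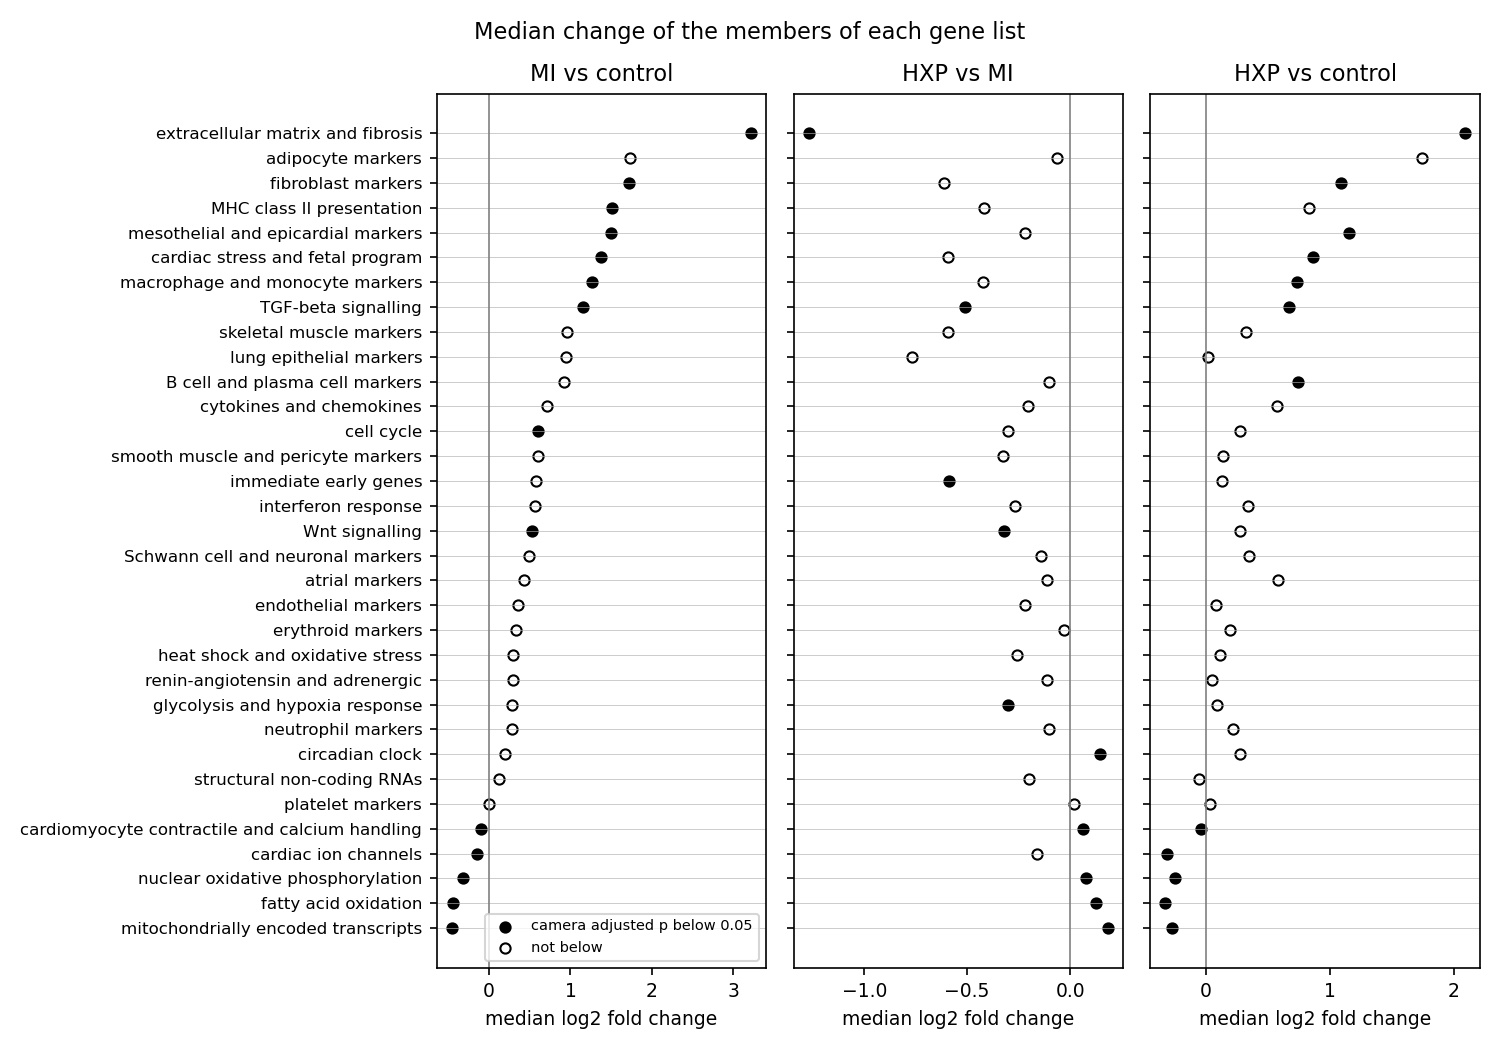
Median log2 fold change of the measured members of 33 gene lists in the 3 comparisons, each panel with its own scale. Filled points mark lists with a limma camera adjusted p below 0.05 at the preset correlation, 14 in MI against control, 10 in HXP against MI and 12 in HXP against control.

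Over all genes, limma called 43 in HXP against control, 13 higher and 30 lower, with 4541 at an unadjusted p below 0.05 (3794 higher, 747 lower) and a median shift of 0.16 (log2). The 30 lower genes had a median GC content of 56.5%, against 49.8% for all genes tested. The count was 0 without control 3, control 5, control 6 or HXP 5, 3 without control 1, 5 without MI 1 or HXP 2 and 7 without control 4 or HXP 3. It was 8 without control 2, 9 without MI 6, 17 without MI 2, 19 without MI 4, 27 without MI 5, 291 without HXP 1 and 4236 without HXP 6. It was 5967 without HXP 5 and HXP 6, an alternative chosen after seeing the data, with 5603 higher and 364 lower. The split was 539 higher and 692 lower after quantile normalization, 534 and 516 after scaling to non-mitochondrial reads, 525 and 745 after median-ratio scaling and 232 and 85 after a GC correction. Within the run of 10 libraries, with 3 controls and 2 HXP, limma called 3 genes, and with the run as a covariate 0.

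The last question was how many of the genes called in MI against control had the opposite call in HXP against MI. Of the 5934 genes called in MI, 0 were called in the opposite direction in HXP against MI. Of the 5494 genes higher in MI, such as Nppa, Col1a1 and Postn, 5212 had a negative fold change in HXP against MI, and 665 of them an unadjusted limma p below 0.05, where independent lists would share 654. Of the 440 genes lower in MI, such as Ces1d, 388 had a positive fold change, 85 of them at an unadjusted limma p below 0.05, where independent lists would share 8.31. These numbers for independent lists leave out the MI libraries that both comparisons share, so an excess over them shows no effect of its own. Because the same MI libraries enter both comparisons, opposite signs can arise without any treatment effect. The medians of all genes also moved in opposite directions (0.27 in MI against control, -0.12 in HXP against MI, log2), so opposite signs were common over all genes. The covariance of the fold changes was -0.0793, and -0.0617 (from -0.0938 to -0.0178) when separate sets of 3 MI libraries entered each comparison. In 100 simulations with the same mean in all 3 groups it averaged -0.0176 (from -0.0702 to 0.00436). Those simulations held no MI effect, so they are not an unchanged HXP group beside the real MI effect. Neither a value outside their ranges nor one within them decides whether genes moved back in HXP. The correlation was -0.582 (simulated from -0.886 to 0.101), the share of all genes with opposite signs 80.2% (simulated mean 63.2%, from 26.6% to 88.4%) and the moved-back count 0 (simulated from 0 to 106). With separate sets of 3 MI libraries the correlation averaged -0.414 (from -0.662 to -0.104) and that share 74% (from 59.1% to 82.7%). Opposite signs thus remained without shared MI libraries. Limma called 0 moved-back genes by voom and by quantile normalization 2, with 10 without HXP 1 and 2 without HXP 3.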

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

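The tests of a swap with a control, of GC content, HXP 5 and HXP 6 alone and an infarct alone on the genes lower in HXP, and of the time of day without Per2 and Tef were chosen only after the result was seen, as were those on genes chosen without both HXP 5 and HXP 6.

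A first pattern was HXP 6 below the controls in extracellular matrix genes, with a mean of 1.37 on the log2 scale against 1.85 to 2.32 in control and 3.62 to 6.33 in the other HXP libraries. GC content bias as the whole cause is argued against by the GC-corrected mean of HXP 6, 1.512, with the lowest other HXP library at 3.641. The highest control mean was 2.321, below the lowest other HXP library at 3.623. This argues against a swap only with an HXP heart at the matrix level of the other HXP libraries. A swapped HXP heart at control level would not show in this test. A mislabelled control is argued against by the position of HXP 6 from control (0) to HXP (1) on genes that set the other HXP libraries apart, 1.271, above the highest held-out control at 0.352, on a measure that can miss an HXP library (HXP 1 at 0.092) but put 0 of 6 controls as high. Since HXP 5, with the same GC trend, had helped to choose those genes, 19 genes lower in HXP were chosen without both: the median of HXP 6 minus the control mean was -1.352, below the lowest of 1000 sets of genes matched in GC content, exon length and level (-0.5) and the lowest control (-0.263, control 2, itself below its own lowest matched set at -0.172; HXP 1 held out stood among the controls here too, at position 0.056), which argues against a mislabelled control with a GC trend, while 50 higher genes decided nothing, since HXP 6 (0.199) and HXP 4 (0.189) both stood within the controls (-0.200 to 0.266). A heart with little or no infarct, or a full response to HXP, stays open and was not tested, nor was what put HXP 6 below the lowest control, at 1.848 after the GC correction.

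A second pattern was the 30 genes lower in HXP than in control, among them Mrpl34, Mrps12 and Hist1h4h. GC content bias as the whole cause is argued against by 26 of the 30 still called lower after the GC correction, with a median log2 fold change of -0.75 (median SE 0.14) before and -0.62 (median SE 0.12) after. Without HXP 5 and HXP 6, 30 of 30 were called lower, at a median log2 fold change of -0.673. That argues against a cause in HXP 5 and HXP 6 alone, though HXP 1 to 4 had helped to choose the genes. The calls themselves depended on which libraries set the spread: without HXP 5 alone 0 of the 30 were called. A difference between runs of library numbers as the whole cause is argued against by control 1, of the run with most HXP libraries, at position 0.173 from control (0) to HXP (1) on 24 genes chosen without it, with HXP 2 at 0.791 and HXP 5 at 1.281 from the other run. An infarct like that of the MI group as the whole cause was not decided. On genes chosen without them, 5 of 6 HXP libraries lay below the lowest MI library, all but HXP 1 (4.116, with MI from 3.703 to 4.209 and the lowest control at 4.079). These values carried no GC correction. In the highest GC bin HXP 4, 5 and 6 lay at -0.182, -0.425 and -0.78, below MI (0.075 to 0.461), so GC content may share in their place. HXP 2 (0.18) and HXP 3 (0.302) lay within the MI range there. The 30 genes had a median log2 fold change of -0.27 in MI against control too, so an infarct as part or all of the cause stays open beside the treatment.

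A further pattern was a set of clock output genes higher in HXP than in MI (Hlf, Per3 and Nr1d2, with Arntl lower). A different time of day of collection cannot be told apart: a phase score over 7 clock genes not past the threshold over the list alone was higher in HXP by 0.356 (2.612 ± 0.347 against 2.256 ± 0.492, SD, n = 6 each, exact permutation p = 0.180), which leaves it open, and Nr1d1 at -0.57 goes against that phase. A score set beforehand, with a difference of 0.578 (exact permutation p = 0.0411), also held Per2 and Tef, which had prompted the pattern, and so decided nothing. On GC-corrected values that score differed by 0.724 (exact permutation p = 0.0130). It held none of Hlf, Per3, Nr1d2 and Arntl, so GC content bias in these genes was not decided. The run of library numbers cannot be told apart, since within the run of 10 libraries the lower of HXP 2 and HXP 5 stood at 2.097, below the highest of the 5 MI libraries at 2.512, and the treatment stays open too, as collection times are not given in the sources used here.

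Other splits of the 12 libraries of each comparison were compared with the real one, 100 of 462 drawn with the real one included. For genes in MI against control 1 split gave as many as the real 5934, the real one itself, with 1 gene in the highest other, so chance can be excluded. For HXP against control 3 splits, the real one among them, gave as many as the real 43, with 1796 in the highest other. That share is low, but it rests on 100 of 462 splits. The 43 also fell to 0 without any 1 of control 3, 5 and 6, so chance is not firmly excluded. The split with 1796 points to a structure of the samples beside the groups. For HXP against MI, where the real split called 0 genes, 100 of 100 gave as many, 13 called more and the highest called 5275, which points to such a structure again. For the number of lists past limma camera, chance cannot be excluded: 31 splits gave as many as the real 14 in MI against control (highest other 22), 71 as many as the real 10 in HXP against MI (highest other 23) and 38 as many as the real 12 in HXP against control (highest other 21). That count sets lists against other genes. The mean of each list on its own passed an exact permutation test after adjustment in 26 of 33 lists in MI against control. This argues against chance for those lists as a set, not for each list. Nuclear oxidative phosphorylation passed at an exact permutation p of 0.0238 (adjusted to 0.0302). Lung epithelial markers passed too (exact permutation p = 0.00216), with MI 5 at 5.41 and the next MI library at 0.28. The test also took MI 1 and MI 2 as separate mice. The list means keep the shift of 0.27 in the median of all genes, so a pass does not show a change particular to the list. Endothelial markers passed with a difference of 0.333, but their limma camera adjusted p was 0.970.

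Groups of 6 libraries were checked 330 times, for named genes, list means and measures of the library such as its reads. In 15 checks 1 library stood apart by its gap to the nearest other as a share of the group's range. Chance gives about 1 in 20, or 16.5, a total that does not speak to the size of any single gap. On the log2 scale, with the share, these 15 were as follows. Control 4 was highest in Angptl7 (0.743, at 1.36 with the next at 0.50), Ctss (0.640, 3.796 and 3.541) and Dkk3 (0.703, 1.26 and 0.90). Control 2 was lowest in Mrpl34 (0.642, 4.84 and 5.72) and the TGF-beta signalling list (0.682, 2.07 and 2.29). MI 6 was lowest in Comp (0.630, 4.52 and 7.45), Sfrp2 (0.643, 4.18 and 7.18) and atrial markers (0.712, 2.06 and 2.52). MI 5 was lowest in Gsta3 (0.856, 0.60 and 0.94) and highest in Maco1 (0.772, 2.79 and 2.54). HXP 3 was highest in Maco1 (0.783, 3.10 and 2.74) and HXP 1 in erythroid markers (0.669, 7.55 and 6.67). MI 5 was highest in lung epithelial markers (0.967, 5.41 and 0.28), MI 4 in skeletal muscle markers of the MI group (0.787, 3.83 and 1.05) and HXP 5 in those of the HXP group (0.891, 1.61 and 0.41).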

How the results depend on the processing

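Scaling to non-mitochondrial reads, median-ratio scaling, the GC corrections, voom, leaving out HXP 5 and HXP 6, averaging MI 1 and MI 2 and the run of 10 libraries were chosen after seeing the data. The 5934 genes of MI against control stayed within 1.5 times under all but these: 2292 at a mean of at least 5 FPKM, where fewer genes were tested, 79 in the run of 10 libraries, with fewer samples, and 2656 to 6972 when 1 library was left out. HXP against MI moved from 0 genes to 4 by quantile normalization, 1 by the replicate block, 1 by non-mitochondrial scaling, 5 by median-ratio scaling, 5 by GC correction with median-ratio scaling, 1 by GC correction with the block, 3 in the run of 10 libraries and 0 to 71 without 1 library. HXP against control moved from 43 to 1231 by quantile normalization, 0 with no filter, 85 at a mean of at least 5 FPKM, 103 at a pseudocount of 0.1, 5 with 2 groups only, 1 by the block, 0 with the run as a covariate, 1050 by non-mitochondrial scaling, 1270 by median-ratio scaling, 317 by GC correction, 1433 by GC correction with median-ratio scaling, 542 by GC correction with the block, 14 by voom, 5967 without HXP 5 and HXP 6, 16 with MI 1 and MI 2 averaged, 3 in the run of 10 libraries and 0 to 4236 without 1 library. Moved-back genes went from 0 to 2 by quantile normalization, 1 by non-mitochondrial scaling, 1 by median-ratio scaling, 1 by GC correction with median-ratio scaling and 0 to 10 without 1 library. Past lists stood at 14, 10 and 12 (MI against control, HXP against MI, HXP against control) and at 0, 0 and 0 with an estimated correlation. That correlation ran from 0.0832 (renin-angiotensin and adrenergic) to 0.954 (skeletal muscle markers), with 0.927 for extracellular matrix genes, against the preset 0.01. The limma camera p at the preset value is thus too small where members move together. In HXP against MI the past lists numbered 17 with no filter and 16 by GC correction with median-ratio scaling. Without 1 library they ran from 12 to 17, 7 to 15 and 10 to 15. The cause of these moves was not tested. The run of 10 libraries held fewer samples, but it also left out MI 5, whose loss alone gave 2656 genes in MI against control.

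Among named genes 1 value changed sign, mt-Nd6 in MI against control, from -0.44 to 0.007 by quantile normalization (limma adjusted p = 0.969, over its alternatives 0.00392 to 0.969). That method sets the most abundant genes, mitochondrial transcripts among them, nearly equal in every library, so the value near 0 follows from the method and shows no change of direction. A change of sign was counted only where either value passed. The replicate numbers did not pair the mice: over 18 pairs with the same number the correlation across genes, which are not independent, ran from -0.313 to 0.635, 5 were over 0.1 and 3 were best with their own number. With the block limma called 5610, 1 and 1 genes and 14, 11 and 14 lists, and with GC correction and block 6156, 1 and 542 genes. The tests planned for counts (edgeR with TMM, RLE or upper quartile, DESeq2 and voom on deposited counts) were not run because the values are FPKM.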

Other observations

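Some cell type markers stood high in part of the MI and HXP hearts. The immunoglobulin light chain gene Igkc rose in MI by a log2 fold change of 4.28 (SE 1.16, limma adjusted p = 0.0154, higher than every control in 5 of 6 libraries), from 5.50 ± 4.29 to 219 ± 241 FPKM (SD, n = 6 each). As a list, B cell and plasma cell markers rose in 7 of 9 members in MI, over all genes and adjusted over the list alone, but the list did not pass at the main scaling (median 0.93, limma camera adjusted p = 0.148). Adipocyte markers were higher in MI in 2 of 10 members over all genes and 0 adjusted over the list alone (median 1.73, limma camera adjusted p = 0.738), with means per library from 1.25 in MI 6 to 4.61 in MI 3, from 0.96 in HXP 6 to 5.49 in HXP 2 and from 1.04 to 1.33 in control. Cytokines and chemokines rose in 11 of 22 members, over all genes and adjusted over the list alone (median 0.71, adjusted p = 0.204), with the chemokine gene Cx3cl1 at 1.54. The interferon response rose in 10 of 24 and 11 adjusted over the list alone (median 0.56, adjusted p = 0.130) and immediate early genes in 9 of 20 and 10 adjusted over the list alone (median 0.58, adjusted p = 0.188), with Egr2 at 1.202. The glycolysis and hypoxia response had 8 members higher and 1 lower of 20, over all genes and adjusted over the list alone (median 0.28, adjusted p = 0.781).

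Smooth muscle and pericyte markers rose in 6 of 15 members in MI against control (7 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 0.977), Schwann cell and neuronal markers in 3 of 5 (3 over the list alone, adjusted p = 0.781), atrial markers in 3 of 9 (3 over the list alone, adjusted p = 0.977), endothelial markers in 2 of 19 (1 over the list alone, adjusted p = 0.970), heat shock and oxidative stress genes in 3 of 16 (2 over the list alone, adjusted p = 0.977) and neutrophil markers in 1 of 8 (0 over the list alone, adjusted p = 0.457). The circadian clock list had 3 higher and 1 lower of 18 (0 over the list alone, adjusted p = 0.0657) and the renin-angiotensin and adrenergic list 4 and 1 of 13 (4 and 1 over the list alone, adjusted p = 0.0897). Erythroid markers (8 measured, adjusted p = 0.189), platelet markers (6, adjusted p = 0.0863) and structural non-coding RNAs (7, adjusted p = 0.0676) had 0 members past. Lung epithelial markers rose in 1 of 7 (0 over the list alone, adjusted p = 0.977) and skeletal muscle markers in 2 of 7 (0 over the list alone, adjusted p = 0.562). The surfactant gene Sftpc stood at 970 FPKM in MI 5 and at 0 to 0.216 FPKM in the other 17 libraries. T and NK cell markers (3 measured) and thymus markers (1 measured) were too few for a test.

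The median of a list and its limma camera direction differed in sign in several lists that did not pass. In MI against control the direction was down with a median above 0 for neutrophil, smooth muscle and pericyte, erythroid, circadian clock, renin-angiotensin and adrenergic, and structural non-coding RNA lists. In HXP against MI it was up with a median below 0 for cardiac ion channels, cytokines and chemokines, renin-angiotensin and adrenergic, structural non-coding RNAs and the neutrophil, B cell and plasma cell, erythroid, adipocyte, atrial, mesothelial and epicardial, and Schwann cell and neuronal markers. In HXP against control it was down with a median above 0 for the glycolysis and hypoxia response, immediate early genes, heat shock and oxidative stress, renin-angiotensin and adrenergic genes and the endothelial, smooth muscle and pericyte, erythroid, neutrophil, platelet, lung epithelial and skeletal muscle markers.

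MI 1 and MI 2 were the most alike pair of MI libraries. Their difference was 7.35 times that of sampling noise, against 35.8 for the next pair of MI libraries, 15.4 for the closest pair of controls and 38.5 for the closest pair of HXP libraries. This does not show whether they came from separate mice, since 2 libraries of 1 heart would also differ by more than sampling noise. They were counted as separate samples, as labelled, and limma called 4202, 0 and 16 genes in the 3 comparisons with both averaged.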
